A study of Homo sapiens with 4 samples.

How the data were processed

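RNA was measured in 4 samples of HEK293T cells, 2 transduced with a control shRNA (shCtrl) and 2 with an shRNA against RPRD1B (shRPRD1B). Per the labels' protocols, RNA was isolated with a column kit and poly(A) RNA libraries were made by a service provider with an Illumina kit. The deposited files hold whole-number read counts per gene, 1 file per sample. The submitters' processing notes name Trim Galore for trimming, HISAT2 for alignment, featureCounts for counting and hg38 as the genome. Versions, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies can therefore not be told apart, and single members of such families are uncertain. Some genes that every cell uses had almost no counts, so a low count here does not show a low level of the transcript. The shRNA sequences are likewise not given in those sources.

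The counts were used as deposited, with totals between 47732913 and 65572391 per library, and no column of per-sample values was left unused. Of 69222 gene identifiers, 62686 matched a symbol by their identifier without its version. The 6536 without a symbol held between 0.216% and 0.239% of the counts of a library and stayed in the tests. Gene symbols, biotypes and coordinates came from reference tables (RefSeq, GRCh38.p14), and transcript sequences, lengths and 3′ UTRs from GENCODE 29, with 1 transcript per gene.

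The main test was edgeR 4.0.16 (R 4.3.3) with its quasi-likelihood fit, robust estimation, TMM factors and the filterByExpr filter with a minimum count of 10. The model had the group as its only term, and p-values were adjusted by Benjamini and Hochberg over the 20319 genes left, with a threshold of 0.05. CPM values, counts scaled to library size, used TMM-scaled library sizes, and log2 CPM used a prior count of 2. Intervals are 95% intervals of the fitted log2 fold change, with SEs from the same fit. A gene at 0 counts in a whole group was set against a floor of 3 counts per library, which covers counting error only. The 2 libraries of each group differed by far more than sampling noise (chi-square per degree of freedom 8.97 for shCtrl and 98.6 for shRPRD1B), so none was a duplicate of another. With groups of 2, no exact permutation of the samples can give a two-sided p under 0.333.

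Genes were named by a rule set before the data were examined. It took the 3 RPRD genes. Among called protein-coding genes with a symbol, a mean of at least 5 CPM and both shRPRD1B libraries on the same side of both shCtrl libraries, it took the 10 largest and 10 smallest fold changes and the 5 higher and 5 lower genes with the smallest p. From each list it took up to 4 members with the smallest p, a few of which are not reported here. Other names are said to be exceptions where they appear.

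The 28 gene lists, also set before the data were examined, covered the RPRD family, Pol II subunits, CTD kinases and phosphatases, cleavage and polyadenylation factors, Integrator subunits, 2 kinds of histone genes, histone mRNA processing factors, G1/S genes, G2/M genes, cyclins with CDKs and their inhibitors, targets of p53, Wnt/beta-catenin and MYC, interferon-stimulated genes, ATF4 and unfolded protein response genes, heat shock and immediate early genes, cholesterol biosynthesis, glycolysis and hypoxia genes, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, small RNAs without a poly(A) tail, extracellular matrix and TGF-beta response genes, and markers of fibroblasts, epithelial cells, leukocytes and neurons. The 26 lists with at least 5 tested members were tested on log2 CPM with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. REST target genes and abundant neuronal transcripts were added as lists after the data had been seen.

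The alternatives planned were size factors by DESeq2's method, upper-quartile factors, library size alone, DESeq2 1.42.0, limma voom, edgeR's older quasi-likelihood fit, no low-count filter, a filter of at least 5 CPM in 2 libraries, the replicate number as a block, leaving out each library in turn, and a fold threshold. Alternatives added after seeing the data were the genes with a symbol only, a correction for transcript length and GC content per library (mgcv 1.9.3), and the genes without ACTAGC in the 3′ UTR.

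The fit was tested on simulated data: counts for the 20319 genes were drawn from the real means, dispersions and library sizes, with 200 genes changed in shRPRD1B against shCtrl. The changed genes all had a mean of at least 5 CPM, so recovery at lower counts was not measured. Both groups were drawn with the same dispersions, although the real shRPRD1B libraries varied more than the shCtrl libraries. Within these limits the fit recovered 64% of the 2-fold changes and 99% of the 4-fold changes, none with the wrong sign. Of its 187 calls, 163 were true and 24 (12.8%) false, above the threshold of 5%, so the adjusted p-values were too small in this simulation. Words in 3′ UTRs were tested by regressing the fold change, limited to 2 on either side of 0, on the presence of each 7-base word found in at least 50 genes. The covariates were 3′ UTR length and GC content, transcript length and expression, over 10743 protein-coding genes with a 3′ UTR of at least 50 bases. As a check, a uniform fall was planted in the genes of a word, in the real log2 ratios between shCtrl 1 and shCtrl 2. There 5 of 5 planted words ranked first. The planted fall was larger than the median shift seen for ACTAGCA, the word reported below (-0.0552 with it, 0.0298 without it). A smaller fall, or a fall in only part of the genes with a word, was not checked. The shRPRD1B libraries varied more, and the check does not cover them. Figures were drawn with matplotlib.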

Results

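Poly(A) RNA was sequenced from HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, after transduction with a lentivirus encoding a short hairpin RNA (shRNA). One group of 2 libraries received a hairpin against RPRD1B (shRPRD1B) and the other group of 2 libraries received a control hairpin (shCtrl). RPRD1B is a regulator that binds the phosphorylated C-terminal domain (CTD) of the largest subunit of RNA polymerase II. The deposited values were read counts per gene. The total counts were 47732913 in shCtrl 1, 48494258 in shCtrl 2, 65572391 in shRPRD1B 1 and 54722140 in shRPRD1B 2. Of 69222 gene identifiers, 20319 had enough counts to be tested. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The control libraries were closer to each other than the knockdown libraries were: among the 8966 genes of at least 16 CPM (counts scaled to the size of each library), the log2 ratio between libraries had an SD of 0.17 for shCtrl and 0.39 for shRPRD1B.

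The first comparison asked whether the hairpin lowered its target. RPRD1B (ENSG00000101413.12, chromosome 20, 38033746 to 38092364 in GRCh38) stood at 50.4 and 50.1 CPM in shCtrl 1 and 2 and at 27.2 and 35.5 CPM in shRPRD1B 1 and 2. Both knockdown libraries lay below both control libraries, the direction their labels give. The group means were 50.2 ± 0.221 and 31.4 ± 5.81 CPM (SD, n = 2 each), and the knockdown level was 0.624 times the control level. The log2 fold change of RPRD1B was -0.68 ± 0.16 (SE), with a 95% interval from -1.08 to -0.29. With edgeR's quasi-likelihood test its p was 0.00587 and its Benjamini-Hochberg adjusted p was 0.448 over all genes, so RPRD1B did not pass the threshold there. It passed when adjusted over the list alone, the list being the 3 RPRD genes (adjusted p = 0.0176), and with DESeq2 (adjusted p = 0.0418). Without shRPRD1B 1 the value was -0.50 and without shRPRD1B 2 it was -0.88 (edgeR adjusted p = 0.000363 and 7.59e-06, in fits where a lone knockdown library has no replicate), and without shCtrl 1 or shCtrl 2 the adjusted p was 1. The paralogue RPRD1A had a mean of 272 CPM in shCtrl and 284 CPM in shRPRD1B (log2 fold change 0.06 ± 0.10, adjusted p = 0.883). RPRD2, the third family member, had 49.3 CPM in shCtrl and 67.7 CPM in shRPRD1B (0.46 ± 0.20, adjusted p = 0.682), and its knockdown libraries lay at 54.6 and 80.8 CPM.

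The second comparison asked which transcripts differed between the groups. The 4 protein-coding genes of at least 5 CPM that edgeR called higher, CRMP1, PTBP2, CPLX1 and SYP, each have a known role in neurons. CRMP1, a cytosolic phosphoprotein of axon guidance, rose from 6.74 ± 0.667 to 40.4 ± 4.37 CPM (SD, n = 2 each). PTBP2, the neuronal polypyrimidine tract-binding splicing regulator, rose from 40.8 ± 1.36 to 149 ± 1.18 CPM. CPLX1 (complexin 1), which controls synaptic vesicle fusion, rose from 13.5 ± 0.301 to 44.8 ± 2.88 CPM, and SYP (synaptophysin), a membrane protein of synaptic vesicles, rose from 25.9 ± 2.33 to 77.7 ± 0.559 CPM. The transcripts that fell included the inducible heat shock protein gene HSPA6, the DEAD-box helicase gene DDX24, the actin-bundling protein gene LCP1, the dehydrogenase gene DHRS2, the annexin gene ANXA5 and DUT, whose product removes dUTP from the nucleotide pool.

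**Figure D1:**
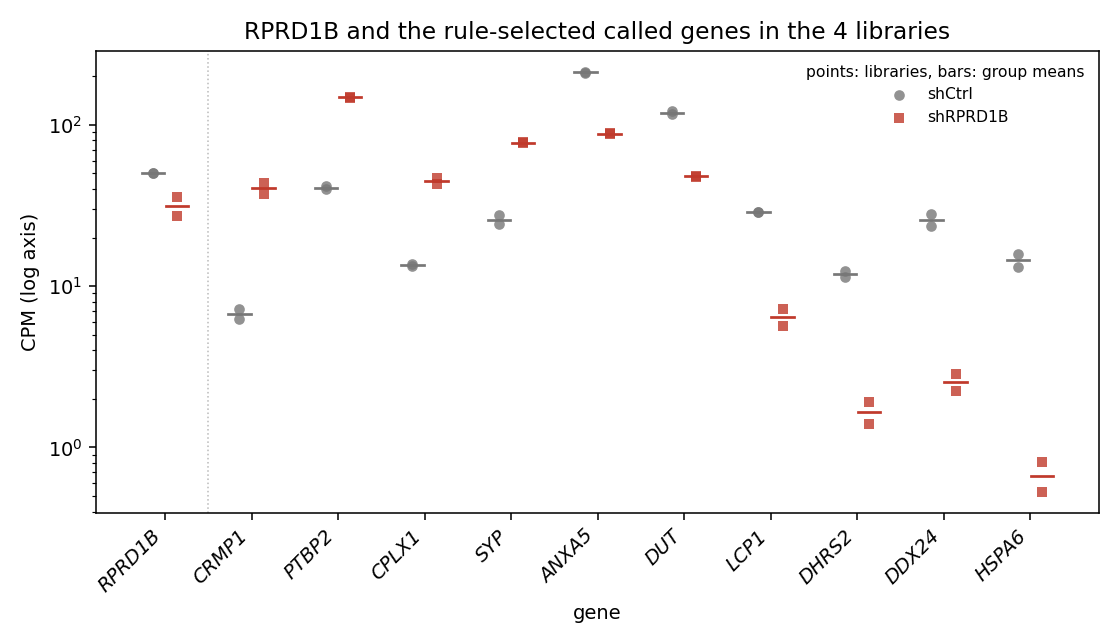
CPM on a log axis for RPRD1B and the 10 protein-coding genes of at least 5 CPM that edgeR called, with grey circles for the 2 shCtrl libraries, red squares for the 2 shRPRD1B libraries and bars for group means. CRMP1, PTBP2, CPLX1 and SYP lay higher in both shRPRD1B libraries, and ANXA5, DUT, LCP1, DHRS2, DDX24 and HSPA6 lay lower.

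Across the 20319 tested genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 6 genes higher and 8 lower in shRPRD1B. The largest rise among the called protein-coding genes of at least 5 CPM was that of CRMP1 (log2 fold change 2.58 ± 0.16, adjusted p = 0.031), followed by PTBP2 (1.87 ± 0.11, adjusted p = 0.031), CPLX1 (1.73 ± 0.13, adjusted p = 0.0414) and SYP (1.59 ± 0.13, adjusted p = 0.0434). HSPA6 had the largest fall among the called protein-coding genes of at least 5 CPM, from 14.5 to 0.669 CPM (-4.42 ± 0.27, adjusted p = 0.031). DDX24 went from 25.9 to 2.55 CPM (-3.35 ± 0.21, adjusted p = 0.031), DHRS2 from 11.9 to 1.65 CPM (-2.85 ± 0.23, adjusted p = 0.0434) and LCP1 from 28.8 to 6.46 CPM (-2.15 ± 0.17, adjusted p = 0.0434). DUT fell from 119 to 48.0 CPM (-1.31 ± 0.11) and ANXA5 from 212 to 88.3 CPM (-1.27 ± 0.11), each with an adjusted p of 0.0468. The 3′ UTRs of DHRS2 and ANXA5 contain the 7-base word ACTAGCA and that of DUT its first 6 bases, ACTAGC, a word that was more common among the lower transcripts. ACTAGC was taken from a 7-base word chosen on these same fold changes, so its shares are a description only. The 6-base word occurs in 53.3% of 120 genes lower and 15.7% of 108 genes higher at an unadjusted edgeR p under 0.01. It also occurs in 14.8% of the 10515 other genes of the word test. Its presence in a single gene therefore does not mark that gene as changed.

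The other 4 called genes fell outside the part of the rule that covers called genes, and are named because they were called, after their values were seen. Of these, RNU6-1 was also taken by the list part of the rule. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, rose from 0.918 to 7.43 CPM (3.02 ± 0.26, adjusted p = 0.0472 with edgeR). Of the 15 tested genes within 250 kb of PCK2, 6 differed over 8-fold between the libraries of 1 group. ENSG00000283018.1, an identifier without a symbol in the tables used, rose from 0.844 to 9.03 CPM (3.42 ± 0.23, adjusted p = 0.0351). RNU6-1, a U6 small nuclear RNA gene whose reads cannot be separated from those of its many near-identical copies, fell from 4.97 to 0.0624 CPM (-6.36 ± 0.48, adjusted p = 0.0406). HBB, the beta-globin gene, had 330 and 364 counts in shCtrl 1 and 2 and 0 counts in both shRPRD1B libraries, which is at least 132-fold lower against a floor of 3 counts per library (adjusted p = 0.0414). Some lentiviral vectors carry beta-globin or U6 sequences, and the vectors were not used here, so it is not known whether the HBB and RNU6-1 counts came from the cells' own genes.

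The count of calls changed with the tool, the filter and the libraries used. At an unadjusted p under 0.05, edgeR gave 721 genes higher and 800 lower, against 1016 expected in all by chance, while DESeq2 called 129 higher and 111 lower and limma voom called 0 (1460 genes at an unadjusted p under 0.05). With the same edgeR fit, 23 genes were called higher and 17 lower with no low-count filter, and 0 and 0 with at least 5 CPM in 2 libraries. Both shRPRD1B libraries lay above both shCtrl libraries, or both lay below them, for 8311 genes, 40.9% of those tested. Chance gives 33.3% only if all libraries vary alike. The shRPRD1B pair varied more (SD of the log2 ratio 0.393, against 0.171 for shCtrl), which raises that share without a group difference. The excess can therefore not be read as an effect of the groups. Leaving out 1 library moved the counts: 20 higher and 36 lower without shCtrl 1, 12 and 42 without shCtrl 2, 3139 and 3096 without shRPRD1B 1, and 1269 and 960 without shRPRD1B 2, where the lone library of a group is assumed to vary like the other group. ANXA5 and DUT were no longer called without shCtrl 1 or without shCtrl 2, nor was SYP without shCtrl 2.

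The third comparison took gene lists around RPRD1B's known partners, RNA polymerase II and the 3′ end machinery. The cleavage and polyadenylation factors had positive fold changes for 25 of 27 tested members, with a median of 0.16. Examples are PAPOLG, a poly(A) polymerase (0.41 ± 0.15), NUDT21, a subunit of the cleavage factor that binds UGUA motifs (0.36 ± 0.15), PABPN1, the nuclear poly(A)-binding protein (0.28 ± 0.12), and SCAF8 (0.49 ± 0.22). Limma's camera called the list (adjusted p = 0.0147) with its preset correlation but not with an estimated one (adjusted p = 0.915 with an estimated correlation). No single member was called by edgeR or DESeq2, and 2 were higher at an unadjusted p under 0.05. The list median was 0.02 in shRPRD1B 1 and 0.27 in shRPRD1B 2, and the camera call was lost without shRPRD1B 2 (0.03, adjusted p = 0.677), without shCtrl 1 (0.13, adjusted p = 0.258) and without shCtrl 2 (0.18, adjusted p = 0.196).

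Other lists of the transcription machinery were not called as lists. The 12 Pol II subunit genes had a median of -0.22 (camera adjusted p = 0.111). Their member with the smallest p was POLR2L at 178 CPM in shCtrl and 138 CPM in shRPRD1B (-0.37 ± 0.11), and it was the only one at an unadjusted p under 0.05. POLR2A, the gene of the largest subunit, which every cell uses, had only 1.07 and 1.16 CPM, so its count cannot be read as its level. It was chosen after its values were seen, as was LDHA of the glycolysis list (0.733 and 0.387 CPM), to which the same limit applies. The 26 CTD kinase and phosphatase genes had a median of 0.09 (camera adjusted p = 0.503), and their mean was 0.01. Within that list, CCNC, the cyclin of the Mediator kinases, had 68.0 CPM in shCtrl and 44.8 CPM in shRPRD1B (-0.60 ± 0.11). It fell when adjusted over the list alone (edgeR adjusted p = 0.0474) and with DESeq2 (adjusted p = 0.00771), against 0.32 over all genes with edgeR. MNAT1, a subunit of the CDK-activating kinase, had 36.8 and 24.6 CPM (-0.58 ± 0.14, adjusted p = 0.46). The word ACTAGC is present in the 3′ UTRs of CCNC and MNAT1, and also in that of CCNT1, which was not lower (0.33 ± 0.15). The 14 Integrator subunit genes had a median of 0.16 (camera adjusted p = 0.293), with 0 called by edgeR or DESeq2 and 0 at an unadjusted p under 0.05. INTS2 gave 0.42 ± 0.17 and INTS14 0.21 ± 0.12, and INTS3 varied from 1.65 to 7.79 CPM within shCtrl and from 11.7 to 36.8 CPM within shRPRD1B.

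Histone mRNAs were examined because most replication-dependent histone transcripts end in a stem-loop rather than a poly(A) tail, and enter a poly(A) library only in part. Of 69 listed replication-dependent genes, 37 had enough counts to be tested, and their median log2 fold change was 0.05 (camera adjusted p = 0.737), while their mean was -0.02. H2BC21 had 2.49 and 4.79 CPM in shCtrl and shRPRD1B (0.95 ± 0.24, adjusted p = 0.505 with edgeR) and H1-5 had 0.531 and 0.222 CPM (-1.28 ± 0.49, adjusted p = 0.66). Those 2 were the members at an unadjusted p under 0.05, and neither edgeR nor DESeq2 called any. Near-identical histone genes can share reads, which makes single members uncertain. Without shRPRD1B 2 the median turned to -0.10, and it was -0.07 with limma voom. The 12 replication-independent histone genes had a median of -0.04 (camera adjusted p = 0.696), with H2AJ at 27.9 and 19.9 CPM (-0.49 ± 0.25). None of these 12 was at an unadjusted p under 0.05 or called by DESeq2. The 14 histone mRNA processing factors had a median of 0.05 (camera adjusted p = 0.333), with LSM11, whose 3′ UTR contains ACTAGC, at 0.33 ± 0.12 and NPAT at 0.35 ± 0.16. Here 1 member was at an unadjusted p under 0.05, and 0 were called by edgeR or DESeq2.

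The fourth comparison took the cell cycle genes that the series title names. Genes of the G1/S program had a median log2 fold change of 0.11 over 43 tested members, of which 31 were positive. POLD3, a DNA polymerase delta subunit, had 48.4 CPM in shCtrl and 62.6 CPM in shRPRD1B (0.37 ± 0.11), ATAD2 gave 0.29 ± 0.14 and RRM1, the large subunit of ribonucleotide reductase, 0.24 ± 0.12. The G1/S list was not called (camera adjusted p = 0.0782, and adjusted p = 0.915 with an estimated correlation). None of its members was called by edgeR over all genes, adjusted over the list alone or by DESeq2, and 1 was at an unadjusted p under 0.05. Camera called the list without shRPRD1B 1 (0.16, adjusted p = 0.00354), and the median was 0.05 without shRPRD1B 2 (adjusted p = 0.591).

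Genes of the G2/M program had a median of 0.07 over 54 tested members, of which 37 were positive, and the list was not called (camera adjusted p = 0.395). HMGB2, a chromatin protein of proliferating cells, had 283 ± 3.99 CPM in shCtrl and 146 ± 11.5 CPM in shRPRD1B (-0.96 ± 0.11). It fell when adjusted over the list alone (edgeR adjusted p = 0.0108) and with DESeq2 (adjusted p = 5.85e-08), against 0.102 over all genes with edgeR, and its 3′ UTR contains the word ACTAGC. CDCA8 had 78.3 and 99.9 CPM (0.35 ± 0.13), CDCA3 73.2 and 60.1 CPM (-0.28 ± 0.12) and HJURP 54.8 and 64.8 CPM (0.24 ± 0.11). The list's median was -0.04 without shRPRD1B 2 (adjusted p = 0.499) and 0.15 without shRPRD1B 1, where camera called it (adjusted p = 0.00502).

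Cyclins, CDKs and CDK inhibitors had a median of 0.06 over 34 tested members (camera adjusted p = 0.323). The G1 kinase gene CDK6 had 82.4 CPM in shCtrl and 56.2 CPM in shRPRD1B (-0.55 ± 0.12, adjusted p = 0.41 with edgeR). DESeq2 called CDK6, whose long 3′ UTR of 10219 bases contains ACTAGCA, and no other member. CDKN1B, encoding the inhibitor p27, gave 0.34 ± 0.11, CCND1 0.36 ± 0.12 and CDK2 0.32 ± 0.12. At an unadjusted p under 0.05 there were 5 higher and 2 lower members, and 0 passed when adjusted over the list alone. The 29 tested p53 target genes had a median of 0.06 (camera adjusted p = 0.393), with RRM2B at 0.44 ± 0.12, PLK2 at 0.57 ± 0.17 and MDM2 at 0.32 ± 0.16, and 2 were at an unadjusted p under 0.05 with 0 called by edgeR or DESeq2.

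Signalling, growth and stress lists were also fixed before the data were examined, and edgeR called none of their members over all genes or adjusted over the list alone. The 21 Wnt/beta-catenin targets had a median of -0.18 (camera adjusted p = 0.664), with JAG1 at 0.57 ± 0.16, DKK1 at -1.23 ± 0.39 and MYC at -0.49 ± 0.17 (171 CPM in shCtrl and 122 CPM in shRPRD1B), and 5 were at an unadjusted p under 0.05. The 28 MYC target genes had a median of 0.00 (camera adjusted p = 0.993) and a mean of -0.05, with FBL at -1.06 ± 0.30, POLR1B at 0.35 ± 0.16 and CAD at 0.23 ± 0.11. Among 19 tested interferon-stimulated genes, 4 were positive and the median was -0.23 (camera adjusted p = 0.111), with IFITM1 at 10.2 and 5.59 CPM (-0.87 ± 0.28) and IFI6 at 16.5 and 9.84 CPM (-0.74 ± 0.36). The 31 immediate early genes had a median of -0.10 (camera adjusted p = 0.111). FOSL1, a subunit of AP-1, had 3.73 and 1.59 CPM (-1.22 ± 0.27) and was the only one of these that DESeq2 called, while DUSP1 gave -0.39 ± 0.11 and EGR1 -0.67 ± 0.20. At an unadjusted p under 0.05 there were 1 MYC target, 2 interferon-stimulated genes and 5 immediate early genes, all of them lower.

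Stress and metabolic programs gave small list medians. The 28 ATF4 and unfolded protein response genes had a median of -0.10 (camera adjusted p = 0.184), and it was 0.04 in shRPRD1B 1 and -0.40 in shRPRD1B 2. SLC7A11, the cystine transporter gene, had 18.3 and 10.8 CPM (-0.75 ± 0.25), SDF2L1 gave -0.36 ± 0.13 and HERPUD1 0.32 ± 0.14. NUPR1 stood below 0.3 CPM in every library (-3.27 ± 0.72). The 17 heat shock response genes had a median of -0.02 (camera adjusted p = 0.953), with HSPB1 at 200 and 126 CPM (-0.67 ± 0.31), HSPH1 at 0.26 ± 0.19 and HSP90AB1 at 0.13 ± 0.11. HSPA1B, which shares reads with HSPA1A, varied from 0.528 to 4.62 CPM within shCtrl. The 24 cholesterol biosynthesis genes had a median of -0.02 (camera adjusted p = 0.696), with EBP at -0.30 ± 0.13. The 27 glycolysis and hypoxia genes had a median of -0.04 (camera adjusted p = 0.645), with KDM3A at 0.34 ± 0.15, HK2 at 0.20 ± 0.11 and PGK1 at -0.27 ± 0.15. HSPA6, which both edgeR and DESeq2 called lower, is not on the heat shock list. Neither called a member of these 4 lists, and 3 ATF4 and unfolded protein response genes and 1 heat shock gene were at an unadjusted p under 0.05.

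Cytosolic ribosomal protein genes were the other list that camera called. Their median was -0.22 over 77 tested members, of which 4 were positive (adjusted p = 8.89e-05 with the preset correlation, and adjusted p = 0.915 with an estimated correlation). RPS15 had 2259 CPM in shCtrl and 1606 CPM in shRPRD1B (-0.49 ± 0.21), RPL38 gave -0.38 ± 0.16, RPS28 -0.44 ± 0.19 and RPL36 -0.53 ± 0.25. No member was called by edgeR or DESeq2 or reached an unadjusted p under 0.05. The list's median was 0.02 in shRPRD1B 1 and -0.49 in shRPRD1B 2, and without shRPRD1B 2 it was 0.02 (adjusted p = 0.944). It was -0.17 without shCtrl 1 (adjusted p = 0.141), -0.26 without shCtrl 2 (adjusted p = 0.00267) and -0.49 without shRPRD1B 1 (adjusted p = 4.51e-13). Fold changes in shRPRD1B 2 also ran with transcript length across 13965 protein-coding genes, which are not independent replicates (Spearman's rho 0.35, against -0.001 in shRPRD1B 1). After a correction for transcript length and GC content, chosen after seeing the data, the list's median was -0.13 (camera adjusted p = 0.00846).

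Mitochondrially encoded mRNAs, with 13 members tested, had a median of 0.07 (camera adjusted p = 0.654), -0.31 in shRPRD1B 1 and 0.44 in shRPRD1B 2. MT-CO1 had 5029 CPM in shCtrl and 7222 CPM in shRPRD1B (0.52 ± 0.15), and MT-ND3 654 and 532 CPM (-0.30 ± 0.14). Of 24 small RNAs that carry no poly(A) tail, 5 could be tested, with a median of 0.15, a mean of -0.99 and a camera adjusted p of 0.696. RNU6-1 was the 1 called member, and RMRP had 0.844 and 1.59 CPM (0.96 ± 0.68) and RN7SL1 21.3 and 25.9 CPM (0.29 ± 0.65).

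**Figure D2:**
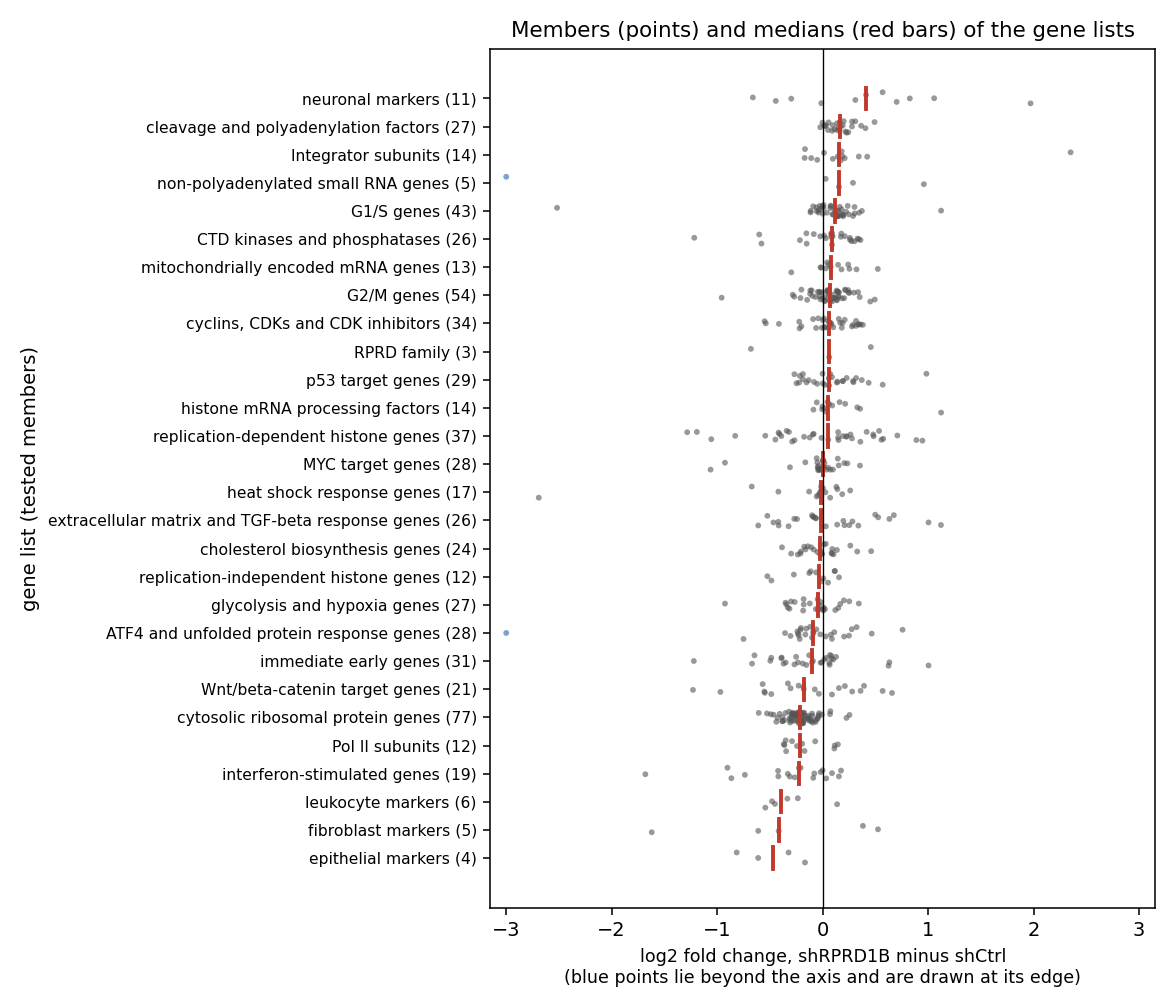
Log2 fold changes (x axis, shRPRD1B minus shCtrl) of the tested members of each gene list (y axis, number of tested members in brackets), with points for genes and red bars for list medians. The cytosolic ribosomal protein genes centre on -0.22, the cleavage and polyadenylation factors on 0.16 and the neuronal markers on 0.41, and members of most lists lie on both sides of 0.

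Marker lists of differentiated cell types were measured as well. Neuronal markers had a median of 0.41 over 11 tested members, of which 7 were positive (camera adjusted p = 0.0782). INA, encoding the intermediate filament protein internexin alpha, had 25.01 ± 2.50 CPM in shCtrl and 40.7 ± 5.06 CPM in shRPRD1B (0.70 ± 0.15). It rose when adjusted over the list alone (edgeR adjusted p = 0.0452) and with DESeq2 (adjusted p = 0.0209), against 0.41 over all genes with edgeR, and its 3′ UTR contains ACTAGC. RBFOX3 had 7.001 and 12.4 CPM (0.83 ± 0.26), SNAP25 0.68 and 1.42 CPM (1.06 ± 0.41) and ELAVL4 0.093 and 0.373 CPM (1.97 ± 0.65). The fry test gave a p of 0.0139 for movement of the list in 1 direction (adjusted p = 0.362) and of 0.00243 for movement in either direction (adjusted p = 0.0631).

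Of 5 tested fibroblast markers, LUM (2.32 and 0.745 CPM, -1.62 ± 0.30) and COL1A1 (30.1 and 19.7 CPM, -0.61 ± 0.15) fell when adjusted over the list alone (edgeR adjusted p = 0.00993 and 0.0169), and neither passed over all genes with edgeR (0.322 and 0.47), while DESeq2 called LUM and not COL1A1 over all genes. The 3′ UTR of LUM contains ACTAGCA, and the list as a whole had a median of -0.42 (camera adjusted p = 0.393). The 26 extracellular matrix and TGF-beta response genes had a median of -0.02 and a mean of 0.08 (camera adjusted p = 0.834), with COL4A2 at 0.50 ± 0.14, COL5A1 at 0.53 ± 0.18 and ID1 at -0.47 ± 0.16. Of these, 6 were at an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. The 6 tested leukocyte markers had a median of -0.39 (camera adjusted p = 0.111), with CORO1A at 13.1 and 10.3 CPM. Only 4 epithelial markers could be tested, too few for a list test, and all 4 were lower in the group mean, with KRT18 at 58.4 and 52.0 CPM (-0.17 ± 0.12) and KRT8 at 26.004 and 14.7 CPM (-0.82 ± 0.57).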

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

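The direction of the called genes held across the settings, and the number of calls depended on them strongly. Every setting used these same libraries. For all 14 called genes both shRPRD1B libraries lay on the same side of both shCtrl libraries, so their sign could hardly change. All 14 called genes kept their sign in every setting that tested them. All 14 were called again with DESeq2's size factors, library size alone, DESeq2, no low-count filter and the replicate block. The fits without shRPRD1B 1 or without shRPRD1B 2 leave a lone knockdown library, so a call there is no test of these genes. PCK2 was lost with upper-quartile factors, 7 of the 14 with the older quasi-likelihood fit of edgeR, all with limma voom, and all 13 that could be tested with at least 5 CPM in 2 libraries. ANXA5 and DUT were lost without shCtrl 1 and without shCtrl 2, and SYP without shCtrl 2. PCK2 was the 1 of 11 lost among genes without ACTAGC in the 3′ UTR. The counts of genes higher and lower were 6 and 8 as reported, 129 and 111 with DESeq2, 0 and 0 with limma voom, 4 and 3 with the older fit, 23 and 17 with no low-count filter, and 0 and 0 with at least 5 CPM. Of the settings chosen after seeing the data, the length and GC correction gave 25 and 21 and the genes without ACTAGC in the 3′ UTR 5 and 5, where fewer genes were tested. With 1 library left out they ranged from 12 to 3139 higher and from 36 to 3096 lower. Without 1 shRPRD1B library the test took its spread from the closer shCtrl pair (SD of the log2 ratio 0.171, against 0.393 for the shRPRD1B pair), but the counts also rose without 1 shCtrl library, to 20 and 36 or 12 and 42, with more genes tested, and the cause was not tested. The labels do not say whether libraries with the same replicate number belong together. Across genes, the difference between shCtrl 1 and 2 and that between shRPRD1B 1 and 2 had a correlation of 0.0134. That value cannot settle the pairing, since each difference also holds the variation of its own libraries. The fit with the replicate number as a block gave 85 and 56 calls.

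Of 26 lists, 2 were called as reported, 0 with an estimated correlation and 0 with fry. The number of lists tested changed with the filter and the libraries: 5 of 22 were called with at least 5 CPM, 0 of 27 without shCtrl 1, 1 of 27 without shCtrl 2, 11 of 26 without shRPRD1B 1 and 3 of 27 without shRPRD1B 2. The G1/S median was 0.104 with at least 5 CPM and 0.103 with the length and GC correction, where camera called it (adjusted p = 0.0305 and 0.036, against 0.00354 to 0.591 over its other settings), and 0.0498 to 0.164 with 1 library left out. The cause was not tested. The G2/M median ranged from -0.0435 to 0.148 with 1 library left out. The histone median, reported as 0.05, was -0.074 with limma voom, -0.132 with at least 5 CPM (2 members left, no test), -0.00311 with the replicate block, and -0.0966 to 0.18 with 1 library left out. These values lie close to 0, and the cause of the sign changes was not tested. The ribosomal protein median ranged from -0.488 to 0.02, the latter without shRPRD1B 2, and was -0.134 with the length and GC correction, where camera called it (adjusted p = 0.00846). RPRD1B was at -0.678 with DESeq2, which called it, and at -0.88 to -0.499 with 1 library left out. The 2 shRPRD1B libraries differed by 98.6 times the counting variance and the 2 shCtrl libraries by 8.97 times, and which limit weighed most on the number of calls was not tested.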

Other observations

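The gene lists of this part, the tests on copies of genes and the genes named in it were chosen after the data had been seen. The tests of the neuronal genes and the 3′ UTR words were fixed before their results were seen. However, 7 members of the list of abundant neuronal transcripts are also in the neuronal marker list, so that test was not blind to their values. The sum over single libraries for DDX24 was chosen after the sum over group means. REST is a repressor that keeps neuronal genes silent in other cells, and a list of 70 of its targets was drawn up without the genes seen among the strongest changes and without the neuronal markers. Of the 52 tested, 45 had a positive fold change and 26 were higher and 0 lower at an unadjusted p under 0.05 with edgeR. None was called over all genes by edgeR or limma voom, DESeq2 called 15 higher and 0 lower, and 25 rose and 0 fell when adjusted over the list alone with edgeR. The sodium channel subunit gene SCN3B had 2.48 CPM in shCtrl and 11.2 CPM in shRPRD1B (2.17 ± 0.33), the active-zone gene BSN 14.5 and 36.5 CPM (1.33 ± 0.20), the calcium channel gene CACNA1B 3.73 and 8.58 CPM (1.20 ± 0.19) and the stathmin gene STMN3 131 and 223 CPM (0.77 ± 0.16).

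CRMP1, CPLX1 and SYP, taken from the called genes, were higher in both shRPRD1B libraries while the fixed neuronal marker list was not called (7 of 11 positive, camera adjusted p = 0.0782), and release of REST targets is a candidate explanation. The median log2 fold change of the REST list was 0.729, above all 10000 random lists of the same size matched on expression. The highest median of those random lists was 0.189. Camera with an estimated correlation gave the REST list a p of 0.0209, not adjusted over the other lists. In the same camera test the unadjusted p of the neuronal markers was 0.119. The adjusted p-values of the fixed lists are therefore not a like comparison. The REST list's median was 0.78 for shRPRD1B 1 against shCtrl 1, 0.55 for shRPRD1B 2 against shCtrl 2 and 0.04 between the control libraries. The data argue against transcript length or GC content, since the median was 0.701 after that correction, and against RNA from neural cells, since the median difference of 15 abundant neuronal transcripts was 0.495 CPM where SYP rose by 51.8 CPM (in shCtrl and shRPRD1B, SNAP25 0.68 and 1.42 CPM, RTN1 7.70 and 14.9 CPM, MAP1B, the 1 that rose by 25 CPM or more, 65.0 and 92.5 CPM, NEFL 107 and 106 CPM, UCHL1 315 and 196 CPM, and TUBB3 0.654 and 0.477 CPM, too few counts to weigh). How REST activity would fall stays open: its mRNA was at 43.8 CPM in shCtrl and 39.96 CPM in shRPRD1B (-0.13 ± 0.19, 95% interval -0.61 to 0.34), its 3′ UTR holds 1 copy of the word described next, and its protein was not measured.

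A 6-base core, ACTAGC, marked the 3′ UTRs of transcripts lower in shRPRD1B, and off-target silencing through the shRNA seed is a candidate explanation. Of 16150 words of 7 bases, ACTAGCA had the most negative t, -15.2, against 6.04 for the most positive word, and the next 5 words shared 6 bases with it; it also ranked first for shRPRD1B 1 against shCtrl 1 (-14.6) and shRPRD1B 2 against shCtrl 2 (-11.2), and had -0.849 between the control libraries. Of 120 genes lower at an unadjusted p under 0.01, 37.5% had ACTAGCA, including HNRNPA0 (396 and 191 CPM), PBK (57.2 and 26.3 CPM), ABT1 (132 and 63.6 CPM) and DNTTIP1 (78.8 and 40.5 CPM), against 4.63% of 108 higher genes and 5.35% of 10515 others, a description only, since the word was chosen on the same fold changes; over all 613 genes with it the median log2 fold change was -0.06, against 0.03 without it, and PGBD5 (1.06) and TMEM121B (1.13) have it and rose. The word occurs 1 time in the RPRD1B mRNA, in the coding part of exon 6 of 7 (chromosome 20, 38066133 to 38066139 in GRCh38) within AAGCATGTCTGTTACTAGCAG, but 19.7% of all 7-base words occur in that mRNA, so the site alone is weak evidence. With 1 hairpin and its sequence not used here, a direct effect of the hairpin on these transcripts and an effect of RPRD1B on transcripts with this word both stay open.

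Some genes varied over 8-fold between the 2 libraries of 1 group, 181 in all, among them CD99 (2.91, 84.0, 129 and 49.6 CPM in shCtrl 1 and 2 and shRPRD1B 1 and 2), PSMB3 (125, 7.73, 7.08 and 3.08 CPM) and LSM14A (24.3, 1.62, 1.44 and 58.7 CPM). Reads divided between copies of a gene on alternate sequences are a candidate explanation: 45.3% of the 181 had no symbol, against 2.02% of the other 20138 tested genes, and 485 of the 488 tested identifiers without a symbol are absent from GENCODE 29, which covers the primary assembly. Of all tested genes, 93.3% had a GENCODE 29 transcript. The annotation release of the counts is not given, so absence from GENCODE 29 does not place an identifier on an alternate sequence. Among the varying genes with a symbol and a position, 38.2% had another such gene within 250 kb, against 2.36% of the others. PCK2 had 6 such neighbours, DCAF11, PSME1, EMC9, TINF2, DHRS1 and NOP9, so its rise may come from the same source. However, PCK2 itself did not vary in this way. Its libraries were close within each group (1.06 and 0.781 CPM in shCtrl, 7.81 and 7.04 CPM in shRPRD1B). The called identifier ENSG00000283018.1 has no symbol either, and whether its rise came from such copies was not tested. Its libraries were close within each group (0.865 and 0.822 CPM in shCtrl, 8.96 and 9.10 CPM in shRPRD1B). For DDX24 the tables decide nothing: 0 of its 2 tested neighbours varied in this way, and of 11 identifiers without a symbol that rose by at least 0.5 of its fall, 2 gave a sum with DDX24 that differed by under 10% between group means (6.87% at the least), but the most stable sum still ranged by 71.9% of its mean over the 4 libraries.

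CHAC1 and DDIT4, chosen after their values were seen, differed between the 2 shRPRD1B libraries, with CHAC1 at 8.93, 8.96, 27.7 and 2.28 CPM and DDIT4 at 137, 133, 318 and 54.5 CPM in shCtrl 1, shCtrl 2, shRPRD1B 1 and shRPRD1B 2. The HBB counts of the control libraries came with few counts of the other globin genes, with HBA1 at 6 and 3 counts and HBA2 at 1 and 4 counts in shCtrl 1 and 2, and HBD, HBG1, HBG2 and HBE1 at 0 in every library. In shRPRD1B 1 and 2, where HBB had 0 counts, HBA1 had 21 and 9 counts and HBA2 10 and 5.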
